A study of Mus musculus with 6 samples.

How the data were processed

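Total RNA of IM8A1 XEN cells was labelled with biotin and hybridised to Affymetrix mouse arrays, 1 array per sample, per the labels. The deposited table holds 1 intensity per probe set and array on a linear scale, and the authors had scaled each array so that the mean after trimming 2% of probe sets at each end was 150. GCOS 1.4 is named, with no role, per the submitters' processing notes. The summary method, background correction, detection calls and genome build are not given in the sources used here, so no coordinates are printed. All 6 columns were used, and no column was left out. Deposited intensities ran from 0.029 to 13461.1, with array medians between 21.89 and 24.17. No array pair shared more than 1 identical value among 45101 probe sets, so no array was a copy of another.

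The values were analysed as log2(intensity + 3.26), where the pseudocount is the median over arrays of the 20th percentile. Array medians on that scale spanned 0.125, above the limit of 0.1 set for keeping the deposited scaling, so the arrays were quantile normalised. That step forces one intensity distribution on all arrays and would hide a change in the total amount of RNA. Probe sets whose mean over the arrays lay below the 40th percentile (log2 3.86, an intensity of about 11.2) were left out. Gene symbols came from the platform annotation: 34958 probe sets had 1 symbol, 932 had several and 9211 had none. Of the first kind 34754 matched a gene identifier in the RefSeq table of assembly GRCm38.p6, and 0 symbols changed. Each gene was represented by its probe set with the highest mean, which left 11925 genes. Of the 83 genes called for BMP2, 45 had another kept probe set, and in 44 of these all of them moved the same way. The exception was Ddr1, whose 5 other probe sets ranged from -0.03 to 2.36. In 10 of the 83 the probe set was of a type that can bind transcripts of several genes.

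All arrays entered one fit in limma 3.58.1 under R 4.3.3 (lmFit, contrasts.fit and eBayes with an intensity trend), with a mean per group, 2 residual degrees of freedom and 4.69 prior ones. The spread came only from the untreated and BMP2 pairs, and the lone activin and combined arrays were assumed to vary like them. The tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. There were 6 comparisons: each treatment against untreated, the combined treatment against BMP2 and against activin A, and the interaction. Groups are reported as mean ± SD with n where they had 2 arrays, and differences as log2 fold change ± SE.

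Shifts of 21 gene lists, of 528 entries with 386 measured, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera was run again with an estimated correlation, which has only 2 degrees of freedom here, and no list call held in any comparison. The smallest adjusted p of that form for BMP2 against untreated was 0.308, and it was not run on simulated data. A call lost there therefore does not show that correlation between genes accounts for it. Fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, called none either (smallest adjusted p = 0.0592). Its form without direction, which tests whether genes of a list change either way, passed for many lists for BMP2. Some of these were not called by camera. Lists overlap: 10 of the 27 visceral endoderm genes and 16 of the 26 parietal endoderm genes stand on another list. The lists, the comparisons and the alternatives below, except where stated, were fixed before the data were examined, as was the rule for named genes. The rule took the called genes with non-overlapping arrays and the largest changes, up to 10 each way for BMP2, 6 for activin A and the combined treatment against untreated, and 4 for the rest. Where no gene passed, it took the 3 genes each way with the smallest p. It added the 2 members of each list with the smallest p for BMP2 and a panel of endoderm and signalling genes, of which Lefty1, Nodal and Cer1 were not among the genes tested. Gene models without an official name were skipped.

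The steps were tested on simulated data with 200 changed genes among 11925. In the design of BMP2 against untreated, 59% of genes changed by 1 on the log2 scale were recovered, 91.3% of those changed by 2 and 98.7% of those changed by 3, with 7.96% false calls. In the design of activin A against untreated these were 35.4%, 86.8% and 97.4%, with 9.07% false calls. The false calls exceeded the nominal 5% in both. A list shifted by 1 was called in 10 of 10 draws, and 2 of 200 unchanged lists were called. In these and the simulations named next, genes were drawn as independent and without a shift between replicates. The estimated correlation was 0.258 for the visceral endoderm list and 0.698 for the cholesterol list, so this rate does not cover false calls of correlated lists. For responses that share the untreated arrays, 100 simulations of unchanged groups gave the chance covariance, and 20 gave the chance position of an unchanged array and its chance overlap with the BMP2 calls.

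The alternatives were the deposited scaling, aligned medians, a pseudocount 4 times smaller or larger, no filter, a filter at the 60th percentile, a prior without trend or with robust estimation, the mean of a gene's probe sets, the replicate number as a block, the untreated and BMP2 arrays alone, and each replicate left out in turn. That block set the lone activin and combined arrays midway between the replicates. A block that places the lone arrays with replicate 1 was added after seeing the data. Probe sets without a symbol or with several stayed out of the comparisons.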

Results

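The series measured messenger RNA on Affymetrix arrays in IM8A1 XEN cells, a line of mouse extraembryonic endoderm stem cells, which derive from the primitive endoderm of the blastocyst. Cells were kept for 6 days in serum-containing medium without added factor, with 20 ng/ml of BMP2, with 30 ng/ml of activin A, or with both. BMP2 and activin A are ligands of the TGF-beta superfamily that act through receptors and Smad proteins that differ only in part. There were 2 untreated arrays, 2 BMP2 arrays, 1 activin array and 1 array of the combined treatment. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Each of the 6 arrays held 45101 probe sets, and 11925 genes were tested. The number of arrays limits the precision, and the activin and combined arrays were assumed to vary like the replicated groups. Log2 values below are of the intensity plus a pseudocount of 3.26, which understates the change of dim genes. No detection calls were used here, so a low level may not lie above background.

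The arrays also split by something other than treatment. The replicate 2 arrays of the untreated and BMP2 groups stood apart from the other arrays. The median absolute log2 difference was 0.244 between the untreated replicates and 0.243 between the BMP2 replicates. It was only 0.157 between untreated replicate 1 and the activin array, and 0.138 between BMP2 replicate 1 and the combined array. Differences within replicate 1 arrays and within replicate 2 arrays are therefore given beside the pooled ones for the called lists of BMP2 and for some others.

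BMP2 raised genes of the visceral endoderm, the absorptive epithelium that surrounds the early embryo. Afp, which encodes the fetal serum protein alpha-fetoprotein, rose 34.8-fold, from a log2 level of 3.83 ± 0.67 (SD, n = 2) to 8.95 ± 0.66 (SD, n = 2), with limma's adjusted p = 0.0072. It rose by 4.18 between the replicate 1 arrays and by 6.07 between the replicate 2 arrays. Apoe, a lipid-carrying apolipoprotein, rose by 4.51 ± 0.21 (log2, SE; adjusted p = 0.0022). Rbp4, the plasma carrier of retinol, rose by 3.51 ± 0.21 and Ttr, the carrier of thyroid hormone, by 2.77 ± 0.20. Of the 27 measured genes on the visceral endoderm list, 10 rose, 1 fell and 16 did not pass. Adjusted over the list alone, 21 rose and 1 fell. Other risers on the list were S100g (4.32 ± 0.44), Fgb (4.06 ± 0.46), Apoa1 (2.89 ± 0.31), Spink1 (2.74 ± 0.14) and Amn (2.50 ± 0.34), the last a subunit of the cubilin receptor for protein uptake. Lrp2, the endocytic receptor megalin, fell by 0.98 on the log2 scale (SE 0.14, adjusted p = 0.048) but not with the mean of its probe sets (adjusted p = 0.118), and Cubn stood at 0.02 ± 0.18, a difference whose sign turned when array medians were aligned and between replicates (0.30 and -0.25). The list's median was 2.26 (camera, adjusted p = 5.51e-22, and adjusted p = 0.308 with an estimated correlation). It was 1.69 between the replicate 1 arrays and 2.17 between the replicate 2 arrays, and 1.307 without BMP2 replicate 2. Mean untreated intensities were 11.2 for Afp, 7.64 for Apoa1, 6.03 for Amn and 1.07 for Fgb, at or below the filter level of 11.2, so their folds rest on a dim baseline.

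**Figure D1:**
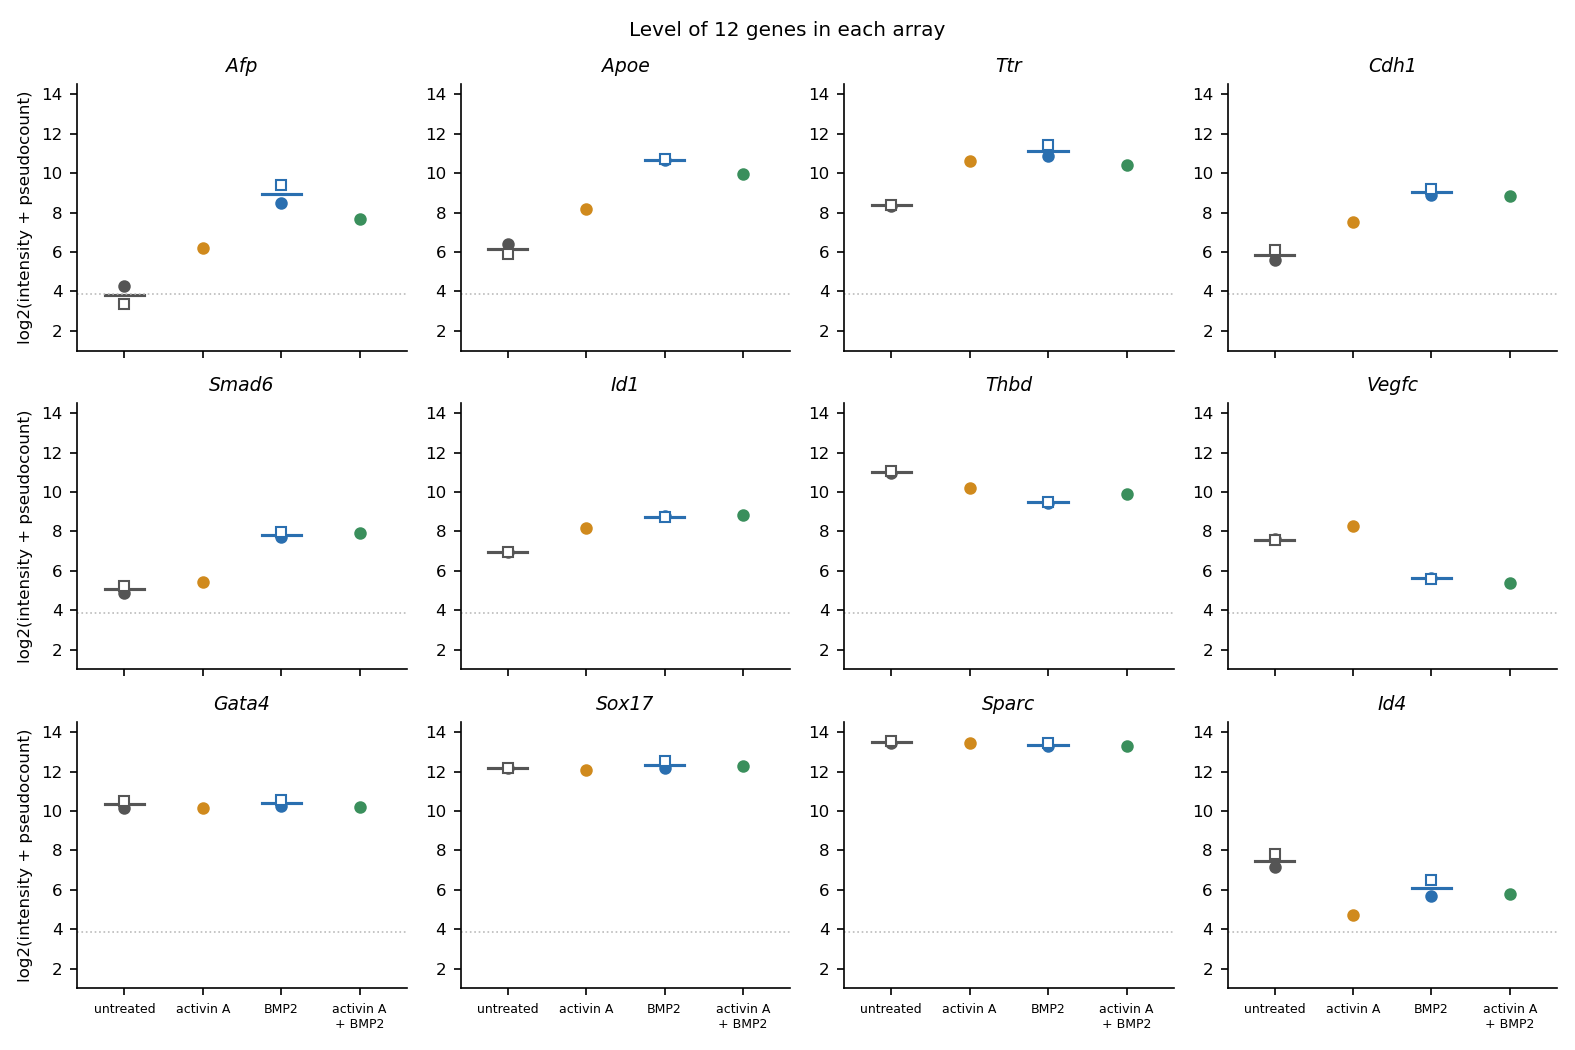
Log2(intensity + pseudocount) of 12 genes in each of the 6 arrays by treatment, with circles for replicate 1 or lone arrays, open squares for replicate 2, bars for the mean of 2 arrays and a dotted line at the filter level of 3.86. Afp, Apoe, Ttr, Cdh1, Smad6 and Id1 rose and Thbd and Vegfc fell with BMP2, while Gata4, Sox17, Sparc and Id4 did not pass the test.

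Genes of epithelial junctions moved with them. Cdh1, which encodes E-cadherin, rose 9.15-fold (log2 3.19 ± 0.24, SE, adjusted p = 0.007), and the tight junction gene Cldn7 rose 6.88-fold. On the list of epithelial junctions and keratins 8 of the 29 measured genes rose, none fell and 21 did not pass, and 21 rose when adjusted over the list alone. Its median was 0.83 (camera, adjusted p = 5.51e-22, and adjusted p = 0.308 with an estimated correlation), with 0.91 between the replicate 1 arrays and 0.86 between the replicate 2 arrays. Zeb1, a transcriptional repressor of E-cadherin, fell by 1.64 on the log2 scale (SE 0.20, adjusted p = 0.025), but with the mean of its probe sets it stood at -0.871 and did not pass (adjusted p = 0.213). It was the only called gene of the 18 on the mesenchymal list, whose median was 0.23 (camera upward, adjusted p = 0.0298, and adjusted p = 0.41 with an estimated correlation), with 0.275 between the replicate 1 arrays and 0.255 between the replicate 2 arrays. That list was not called without BMP2 replicate 1 (0.187, adjusted p = 0.0951), and its median was 0.352 without untreated replicate 1. Tagln on that list stood at 2.87 ± 0.52, Vim at -0.66 ± 0.19 and Snai1 at -0.54 ± 0.40, all without passing.

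Among genes that respond directly to BMP signalling, Smad6, an inhibitory Smad, rose by 2.78 ± 0.23 and Id1, a dominant-negative helix-loop-helix factor, by 1.79 ± 0.17 (adjusted p = 0.0072 and 0.011). Bmper, a secreted BMP-binding protein, fell by 1.60 on the log2 scale (SE 0.19). Of the 21 measured BMP-Smad targets these were the called members, 2 up and 1 down, against 6 up and 2 down when adjusted over the list alone. The list's median was 0.31 (camera, adjusted p = 0.00365, and adjusted p = 0.308 with an estimated correlation), with 0.211 between the replicate 1 arrays and 0.335 between the replicate 2 arrays. Id3 stood at 2.70 ± 0.49, Id2 at 0.68 ± 0.15, Smad7 at 0.51 ± 0.22, Msx2 at 0.22 ± 0.25 and Bambi at -0.14 ± 0.19, and none of them passed. No member of the 14 activin-Smad targets was called (camera, adjusted p = 0.14), with Cdkn2b at 0.86 ± 0.22, Skil at 0.77 ± 0.20 and Fst at -0.12 ± 0.17.

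The parietal endoderm list, of the migratory cells that lay down Reichert's membrane, had a median of -0.14 over 26 genes (camera downward, adjusted p = 0.00365, and adjusted p = 0.345 with an estimated correlation), with -0.123 between the replicate 1 arrays and -0.137 between the replicate 2 arrays. It was not called without BMP2 replicate 1 (-0.058, adjusted p = 0.0666) or untreated replicate 2 (-0.07, adjusted p = 0.0965), and its median was -0.215 without untreated replicate 1 and -0.237 without BMP2 replicate 2. Thbd, which encodes thrombomodulin, was its only called member and fell by 1.53 on the log2 scale (SE 0.14, adjusted p = 0.0081), while 3 fell when adjusted over the list alone. Sparc (-0.13 ± 0.09), Lama1 (-0.18 ± 0.09), Nid1 (-0.61 ± 0.14) and Plat (-0.35 ± 0.18) did not pass. The basement membrane and collagen list, which shares genes with it, had a median of -0.19 over 26 genes (camera downward, adjusted p = 0.00782, and adjusted p = 0.308 with an estimated correlation), with -0.123 between the replicate 1 arrays and -0.163 between the replicate 2 arrays. It was not called without untreated replicate 2 (-0.115, adjusted p = 0.16) or BMP2 replicate 1 (-0.11, adjusted p = 0.0666). Its only called member, Agrn, rose by 1.35 ± 0.16, and Crtap stood at -0.71 ± 0.13. None of the 14 regulators of extraembryonic endoderm passed. Gata4 stood at 0.07 ± 0.18 and Sox17 at 0.15 ± 0.13, both of which turned sign when array medians were aligned. Gata6 stood at -0.89 ± 0.30, Sox7 at -1.05 ± 0.25 and Klf6 at 0.57 ± 0.15. That list's median was 0.11 and its mean -0.05 (camera, adjusted p = 0.618). Hnf4a at 1.52 ± 0.28, Ihh at 1.25 ± 0.43 and Foxa2 at 0.36 ± 0.23 did not pass either.

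Other genes with large rises were Igfbp2 (3.57 ± 0.25), Igf2 (3.24 ± 0.26), Gpc3 (3.22 ± 0.28), Lgals2 (4.06 ± 0.33) and Pyy (4.10 ± 0.54), of insulin-like growth factor signalling in the case of Igf2 and its binding protein Igfbp2. Among called genes the largest falls were those of Pi16 (-3.79 ± 0.45), Slc6a2 (-2.22 ± 0.25, but -0.973 and not called with the mean of its probe sets), the lymphangiogenic factor Vegfc (-1.97 ± 0.19), Kcnq5 (-1.97 ± 0.27), Sp8 (-1.89 ± 0.22) and Gnai1 (-1.79 ± 0.23), beside the chromatin protein gene Hmga2 (adjusted p = 0.014). Lipid handling genes shifted upward as a list (median 0.35 over 21 genes; camera, adjusted p = 0.000228, and adjusted p = 0.308 with an estimated correlation), with 3 called. Their median was 0.361 between the replicate 1 arrays and 0.418 between the replicate 2 arrays, 0.568 without untreated replicate 1 and 0.586 without BMP2 replicate 1. Adjusted over the list alone, 8 rose and 1 fell.

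The remaining called lists rested on 1 called gene or none. The 19 cholesterol genes had a median of 0.42 with none called (camera, adjusted p = 0.00126, and adjusted p = 0.514 with an estimated correlation). Fdft1 stood at 0.89 ± 0.20 and Tm7sf2 at 1.15 ± 0.29. Their median was 0.19 between the replicate 1 arrays and 0.65 between the replicate 2 arrays. They were not called without untreated replicate 1 (0.272, adjusted p = 0.112) or BMP2 replicate 2 (0.106, adjusted p = 0.705), and their median was 0.776 without untreated replicate 2 and 0.943 without BMP2 replicate 1. The 36 cell cycle genes had a median of -0.13 with none called (camera downward, adjusted p = 0.00365, and adjusted p = 0.41 with an estimated correlation), Mki67 standing at -0.36 ± 0.12 and Aurka at -0.32 ± 0.13. That median was -0.15 between the replicate 1 arrays, -0.107 between the replicate 2 arrays and -0.239 with array medians aligned, and the list was not called without untreated replicate 1 (-0.092, adjusted p = 0.207). The 14 cell cycle inhibitors had a median of 0.22 (camera, adjusted p = 0.0238, and adjusted p = 0.308 with an estimated correlation), with Cdkn1c at 2.64 ± 0.50 and Gadd45g at 0.81 ± 0.16, and 3 rose when adjusted over the list alone. Their median was 0.177 between the replicate 1 arrays and 0.147 between the replicate 2 arrays, and they were not called without untreated replicate 2 (0.185, adjusted p = 0.0712) or BMP2 replicate 1 (0.143, adjusted p = 0.0666). The 11 interferon response genes had a median of 0.20 (camera, adjusted p = 0.0182, and adjusted p = 0.308 with an estimated correlation), with Oasl2 at 1.90 ± 0.43 and Bst2 at 1.10 ± 0.26, neither passing. Their median was 0.3 between the replicate 1 arrays and 0.262 between the replicate 2 arrays, 0.299 without untreated replicate 2 and 0.3 without BMP2 replicate 2, and they were not called without untreated replicate 1 (0.246, adjusted p = 0.129). The 26 components of the BMP and activin pathways had a median of 0.17 (camera, adjusted p = 0.0399, and adjusted p = 0.308 with an estimated correlation), with Tgfb2 at 1.36 ± 0.26 and Smad1 at 0.71 ± 0.17. Their median was 0.211 between the replicate 1 arrays and 0.135 between the replicate 2 arrays. Leaving out any 1 of the 4 replicates ended their call, with 0.099 and 0.151 without untreated replicate 1 and 2 (adjusted p = 0.312 and 0.0714) and 0.172 and 0.182 without BMP2 replicate 1 and 2 (adjusted p = 0.0785 and 0.282). The 6 mesendoderm genes, of which Pyy alone was called, had a median of 0.35 (camera, adjusted p = 0.0182, and adjusted p = 0.308 with an estimated correlation), but 0.138 without the filter on dim probe sets and 0.153 with the filter at the 60th percentile, not called under either. It was 0.415 between the replicate 1 arrays and 0.311 between the replicate 2 arrays, 0.589 without untreated replicate 2, and not called without untreated replicate 1 (0.119, adjusted p = 0.129) or BMP2 replicate 2 (0.078, adjusted p = 0.272). With the 60th percentile filter the cell cycle inhibitors (median 0.106, adjusted p = 0.123), the interferon list and the pathway components (adjusted p = 0.0647 for both) were not called. The 21 unfolded protein and heat shock genes had a median of -0.07 (camera downward, adjusted p = 0.0192, and adjusted p = 0.389 with an estimated correlation), although the only called member, the small heat shock protein gene Hspb1, rose by 1.77 ± 0.23. Chac1 on that list stood at -1.97 ± 0.41. The list's median was -0.181 between the replicate 1 arrays and -0.109 between the replicate 2 arrays. It was not called without untreated replicate 2 (-0.144, adjusted p = 0.0912) or BMP2 replicate 1 (-0.025, adjusted p = 0.31), and its median was -0.175 without untreated replicate 1 and -0.187 without BMP2 replicate 2.

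Lists of other cell types that a culture could hold were not called for BMP2 with all arrays. The adjusted camera p was 0.621 for pluripotent cells (8 genes), 0.121 for trophoblast (7 genes) and 0.785 for fibroblast feeders (10 genes, median -0.06 and mean 0.18), with no gene called on any of them. Fry without direction, which does not compare a list with other genes, passed for each of them (adjusted p = 0.00603, 0.0412 and 0.0412 in that order). By the same test the anterior visceral endoderm (adjusted p = 0.0127) and endocytosis lists (adjusted p = 0.007) passed. The trophoblast median of 0.479 was above those of the lipid, BMP-Smad and mesenchymal lists. That list was called under 2 of 15 alternatives, with array medians aligned (0.461, adjusted p = 0.0481) and without untreated replicate 2 (0.678, adjusted p = 0.0495), and its median was -0.027 without the filter on dim probe sets. Utf1 stood at 0.80 ± 0.32, Klf4 at 0.57 ± 0.24, Plac1 at 0.84 ± 0.21, Ets2 at 0.81 ± 0.31, Col6a1 at -1.50 ± 0.26 and Col1a1 at 2.26 ± 0.41. The anterior visceral endoderm list (8 genes, camera adjusted p = 0.121) held Sema6d at -2.24 ± 0.35 and Amot at 1.43 ± 0.30, neither passing, and was called without untreated replicate 2 (0.633, adjusted p = 0.0412). The endocytosis and lysosome list, which holds Amn and Lrp2, was not called (24 genes, median 0.05; camera, adjusted p = 0.383).

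In all, 83 of the 11925 genes changed with BMP2, 64 higher and 19 lower, and 81 of them by at least 2-fold. At an unadjusted p under 0.05 there were 1331 genes, where 596 would be expected by chance. The count moved with the settings: without an intensity trend in limma's prior it was 0 (smallest adjusted p = 0.0628, 1291 genes at an unadjusted p under 0.05), and without the filter on dim probe sets it was 29. With the replicate number as a block it was 981, with all 83 among them. Leaving out untreated replicate 1 or 2 gave 330 or 235 genes, and leaving out BMP2 replicate 1 or 2 gave 21 or 32. Of the 83 genes, 82, 82, 20 and 24 remained in these runs. Among those of the 83 that the rule named, Id1, Bmper, Zeb1, Apoa1, Amn, Lrp2, Agrn, Pyy, Pi16, Slc6a2, Hmga2, Vegfc, Kcnq5, Sp8 and Tnnt1 did not pass when BMP2 replicate 1 or 2 was left out. Nor did Fgb, Gnai1, Thbd and Hspb1 without BMP2 replicate 1 or Lrp2 without untreated replicate 2. Of the 14 called lists these kept 9, 9, 8 and 11, the visceral endoderm, epithelial junction, lipid and BMP-Smad lists in each.

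**Figure D2:**
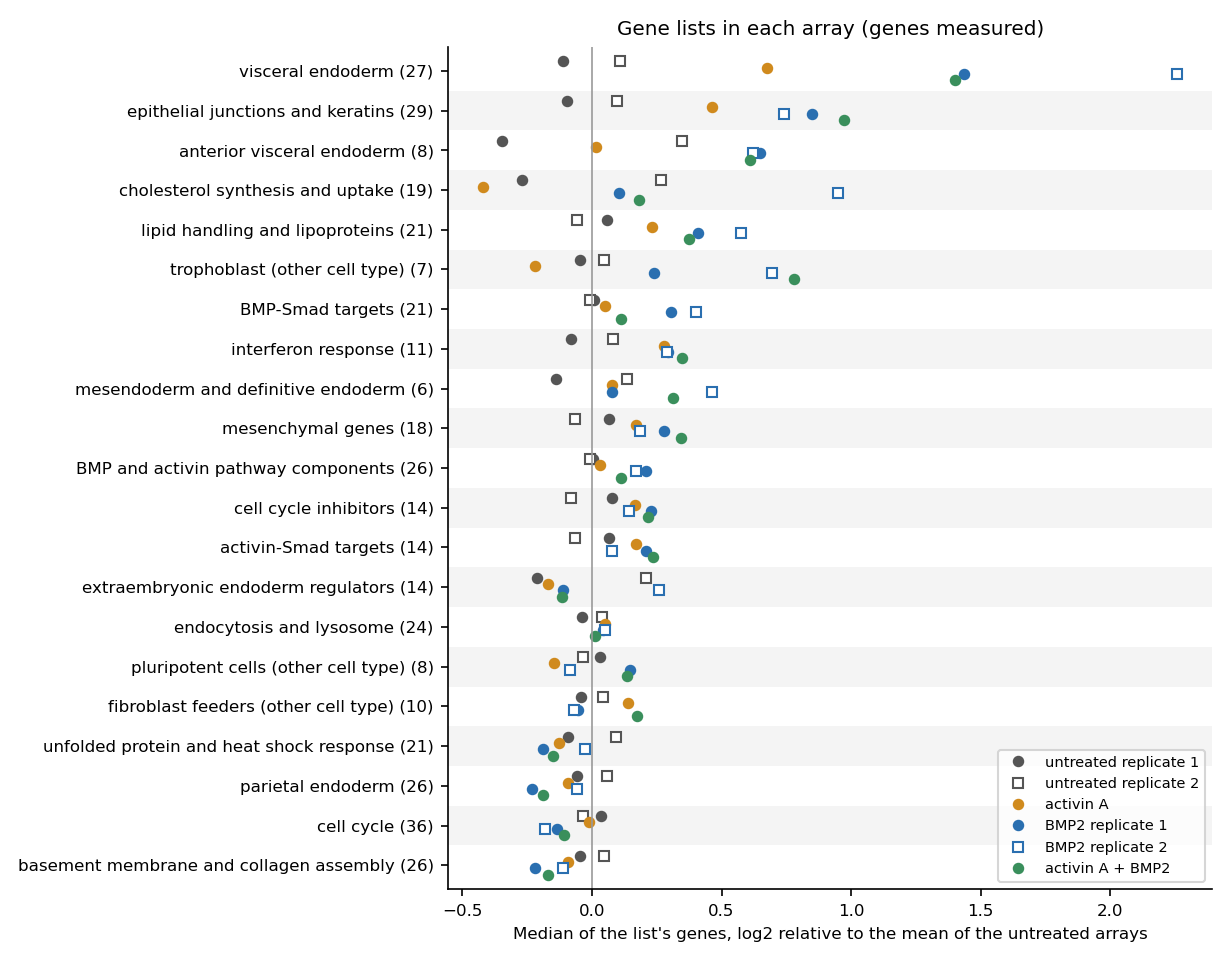
Median over each gene list of the log2 level in each array, relative to the mean of the untreated arrays, with the number of measured genes in brackets, circles for replicate 1 or lone arrays and open squares for replicate 2. The visceral endoderm list lies at 0.674 in the activin array, 1.434 and 2.258 in the BMP2 arrays and 1.402 in the combined array.

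Activin A alone was compared with the untreated arrays to see what the ligand does by itself. No gene passed limma's test, and 453 had an unadjusted p under 0.05, where 596 would be expected by chance. With fewer genes than expected, the lack of calls does not show that activin A changed no gene. Counts with a replicate block are given below. The genes with the smallest p were Ttr (2.24 ± 0.25), Spink1 (1.52 ± 0.17) and Rbp4 (2.14 ± 0.25) above untreated, each with adjusted p = 0.34. Below untreated they were the helix-loop-helix gene Id4 (-2.77 ± 0.43), Tubb3 (-1.80 ± 0.29) and Ccdc138 (-2.12 ± 0.41). Of the panel of endoderm and signalling genes, Afp stood at 2.38, Cdh1 at 1.66, Id1 at 1.19, Id3 at 1.99, Id2 at 0.88 and Cubn at 0.66. Smad6 stood at 0.37, Thbd at -0.83, Gata6 at -0.81 and Snai1 at -0.80. Several of these moved with the untreated array used. Against untreated replicate 1 and 2, Smad6 stood at 0.55 and 0.19, Gata6 at -0.6 and -1.03 and Snai1 at -0.4 and -1.21. In the same order Id3 stood at 1.17 and 2.82, Afp at 1.91 and 2.85 and Cubn at 0.86 and 0.45. Hnf4a stood at -0.14 (0.18 against untreated replicate 1 and -0.47 against untreated replicate 2) and Fst at -0.10 (0.03 and -0.23), and Sparc at -0.07, which turned positive with the deposited scaling.

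As a list, visceral endoderm genes stood higher in the activin array (median 0.67 over 27 genes; camera, adjusted p = 2.25e-12, and adjusted p = 0.59 with an estimated correlation), with 6 raised when adjusted over the list alone. Their median was 0.87 above untreated replicate 1 and 0.47 above untreated replicate 2. Epithelial junction genes had a median of 0.46 (camera, adjusted p = 8.97e-07, and adjusted p = 0.59 with an estimated correlation), with 2 raised when adjusted over the list alone. Lipid handling genes had a median of 0.23 (camera, adjusted p = 0.021, and adjusted p = 0.59 with an estimated correlation). Cholesterol genes had a median of -0.42 (camera downward, adjusted p = 0.00061, and adjusted p = 0.602 with an estimated correlation). The unfolded protein and heat shock genes had a median of -0.13 (camera downward, adjusted p = 0.00473, and adjusted p = 0.59 with an estimated correlation). The other 16 lists were not called, among them the activin-Smad targets (median 0.17, adjusted p = 0.555) and the 3 lists of other cell types. Leaving out untreated replicate 1 or 2 gave 32 or 10 called genes instead of 0, and the cholesterol call ended without untreated replicate 2 (-0.201, adjusted p = 0.0528) and with the block placing the lone arrays with replicate 1 (-0.119, adjusted p = 0.187), while the median was -0.654 without untreated replicate 1. The unfolded protein median was -0.286 without untreated replicate 1. The lipid call ended without the filter on dim probe sets (adjusted p = 0.0765) and with a pseudocount 4 times larger (adjusted p = 0.0676). Other lists were called when 1 array was left out: anterior visceral endoderm (-0.618) and the regulators (-0.368) without untreated replicate 1, and endocytosis (0.104), interferon (0.127) and fibroblast feeders (0.24), a list of another cell type, without untreated replicate 2. Without BMP2 replicate 1 they were parietal endoderm (-0.094), the regulators (-0.168) and interferon (0.279), and without BMP2 replicate 2 parietal endoderm (-0.095) and the regulators (-0.17). The processing also added calls. Endocytosis (0.108 and 0.047) and interferon (0.284 and 0.223) were called with the deposited scaling and with array medians aligned. With the mean of a gene's probe sets they were parietal endoderm (-0.128), the regulators (-0.263) and interferon (0.278).

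The combined treatment was compared with the untreated arrays in the same way. Apoe rose by 3.77 ± 0.25, Igfbp2 by 3.67 ± 0.31, Igf2 by 3.22 ± 0.32, Cdh1 by 2.98 ± 0.29, Rbp4 by 2.94 ± 0.25 and Smad6 by 2.86 ± 0.28, with adjusted p between 0.015 and 0.04. Id1 rose by 1.89 ± 0.20 but did not pass without BMP2 replicate 1 or 2 (adjusted p = 0.063 and 0.062). Vegfc was the 1 gene that fell, by 2.21 on the log2 scale (SE 0.23, adjusted p = 0.043), but with the mean of its probe sets it did not pass (-2.333, adjusted p = 0.0526) and no gene was called lower. Afp stood at 3.84 ± 0.51 (adjusted p = 0.07), Ttr at 2.07 ± 0.25, Id3 at 2.90 ± 0.60, Amn at 2.70 ± 0.42, Thbd at -1.13 ± 0.17 and Gata6 at -1.20 ± 0.37, none of them passing. In all 13 genes changed, 12 higher and 1 lower, and 1019 had an unadjusted p under 0.05, where 596 would be expected by chance.

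Of the 27 visceral endoderm genes 2 rose with the combined treatment and 25 did not pass, while 14 rose and 1 fell when adjusted over the list alone. The median was 1.402 (camera, adjusted p = 5.02e-15, and adjusted p = 0.35 with an estimated correlation), with 1.5 above untreated replicate 1 and 1.2 above replicate 2. Epithelial junction genes had a median of 0.97 with 1 called and 20 raised when adjusted over the list alone (camera, adjusted p = 9.79e-20, and adjusted p = 0.35 with an estimated correlation). The lipid handling (0.37), mesenchymal (0.35) and BMP-Smad target (0.11) lists also shifted upward, and the parietal endoderm (-0.19), basement membrane (-0.17) and unfolded protein (-0.15) lists downward, each with adjusted p = 0.35 with an estimated correlation. The trophoblast list, of another cell type, had a median of 0.781 over 7 genes, above those of the lipid, mesenchymal and BMP-Smad lists, and was not called (camera, adjusted p = 0.053), but it was called under 6 of 14 alternatives, among them without untreated replicate 2 (0.849, adjusted p = 0.00817) and without BMP2 replicate 1 or 2. The lists of pluripotent cells (0.135, adjusted p = 0.73) and fibroblast feeders (0.174, adjusted p = 0.623) were not called. With the deposited scaling the parietal endoderm and basement membrane medians were both -0.06 and, like the BMP-Smad list, not called, and with array medians aligned both were -0.14 and not called. With the mean of a gene's probe sets the BMP-Smad median was -0.061 (adjusted p = 0.135) and the basement membrane list was not called (adjusted p = 0.0716). Without the filter on dim probe sets neither the BMP-Smad (adjusted p = 0.0805) nor the basement membrane list (adjusted p = 0.0636) was called. The BMP-Smad call also ended with a replicate block (adjusted p = 0.094), and the basement membrane call with the block placing the lone arrays (-0.097, adjusted p = 0.054). Leaving out 1 of the 4 replicates ended calls of the parietal endoderm, basement membrane and BMP-Smad lists alone, keeping 6, 6, 7 and 7 of the 8. The BMP-Smad median was 0.023 without untreated replicate 1, 0.056 without BMP2 replicate 1 and 0.114 without BMP2 replicate 2, the parietal endoderm median -0.113 without untreated replicate 2, and the basement membrane median -0.196 and -0.092 without untreated replicate 1 and 2, none of these called. The mesenchymal median was 0.536 without untreated replicate 2 and the unfolded protein median -0.258 without untreated replicate 1. Other lists were called without untreated replicate 2, namely anterior visceral endoderm (0.733), mesendoderm (0.442), cell cycle (-0.143), cholesterol (0.442) and interferon (0.285), and the regulators (-0.315) without untreated replicate 1. The 13 called genes became 0 without the intensity trend in the prior, 0 without the filter on dim probe sets and 27 with array medians aligned. They became 252 or 128 without untreated replicate 1 or 2, and 30 or 29 without BMP2 replicate 1 or 2.

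Adding activin A to BMP2 was read from the combined array against the BMP2 arrays. Limma called no gene, with 189 at an unadjusted p under 0.05, where 596 would be expected by chance. With fewer than expected, the lack of calls does not show that no gene changed. The genes with the smallest p were Ttyh3 (1.28 ± 0.31), Gng4 (2.52 ± 0.62) and Omp (1.81 ± 0.45) above, and Nup54 (-1.33 ± 0.21), Tmem229a (-2.26 ± 0.44) and Zap70 (-2.39 ± 0.47) below, each with adjusted p = 1. The visceral endoderm list stood lower in the combined array, with a median of -0.36 (camera, adjusted p = 3.2e-06, and adjusted p = 0.73 with an estimated correlation). That median was -0.20 against BMP2 replicate 1 and -0.53 against BMP2 replicate 2. The mesenchymal list stood higher at 0.19 (camera, adjusted p = 0.0232, and adjusted p = 0.73 with an estimated correlation), with 0.104 against BMP2 replicate 1 and 0.334 against BMP2 replicate 2. The cholesterol list stood lower at -0.27 (camera, adjusted p = 0.0169, and adjusted p = 0.73 with an estimated correlation), but its median was 0.10 against BMP2 replicate 1 and -0.72 against BMP2 replicate 2. Without BMP2 replicate 2 none of these 3 lists was called, visceral endoderm included (medians of -0.124 for visceral endoderm, adjusted p = 0.191, and of 0.108 for mesenchymal and 0.102 for cholesterol genes, adjusted p = 0.498 for both). Without BMP2 replicate 1 the medians were -0.565, 0.334 and -0.717 in that order, and the mesenchymal call also ended without the filter on dim probe sets (adjusted p = 0.182), with the mean of a gene's probe sets (adjusted p = 0.348) and with the block placing the lone arrays (adjusted p = 0.0612). The parietal endoderm list, at -0.01, stood at 0.20 with the deposited scaling and 0.23 with array medians aligned, and was called upward under both. So were the basement membrane (0.159 and 0.181) and cell cycle (0.092 and 0.115) lists, while the lipid list (-0.175 and -0.153) was called downward under both. Other lists were called without BMP2 replicate 1, namely the regulators (-0.311), mesendoderm (-0.408), unfolded protein (-0.353) and lipid handling (-0.214), the last also without untreated replicate 1 (-0.174) or 2 (-0.139). Leaving out untreated replicate 1 or 2 gave 1 called gene each.

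Adding BMP2 to activin A was read from the combined array against the activin array, 1 array on each side. No gene passed limma's test, with 489 at an unadjusted p under 0.05, where 596 would be expected by chance. Here too the lack of calls does not show that no gene changed, and counts with a replicate block are given below. Smad6 (2.48 ± 0.32) and the troponin genes Tnnc1 (1.88 ± 0.26) and Tnnt1 (3.75 ± 0.58) had the smallest p above the activin array. Vegfc (-2.89 ± 0.27), the aminopeptidase gene Enpep (-1.47 ± 0.17) and Sp8 (-2.33 ± 0.30) had the smallest p below it, with adjusted p = 0.23 for Vegfc. The epithelial junction list had a median of 0.65 (camera, adjusted p = 5.98e-16, and adjusted p = 0.577 with an estimated correlation), and the visceral endoderm list 0.66 (camera, adjusted p = 0.00014, and adjusted p = 0.577 with an estimated correlation). The cholesterol (0.58), mesenchymal (0.32) and BMP-Smad target (0.24) lists were also called upward, each with adjusted p = 0.577 with an estimated correlation. So was the trophoblast list, a list of another cell type, with a median of 1.20 over 7 genes (camera, adjusted p = 0.00142, and adjusted p = 0.577 with an estimated correlation), but 0.152 over 13 genes and not called without the filter on dim probe sets (adjusted p = 0.219). The BMP-Smad list was not called without that filter, nor the mesenchymal list with the mean of a gene's probe sets. The mesendoderm list was called without untreated replicate 1 or 2 (0.242 and 0.244), and the lipid list without either of these or BMP2 replicate 1 (0.216, 0.212 and 0.258). Leaving out untreated replicate 1 or 2 gave 23 or 11 called genes instead of 0.

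Whether the ligands added up was tested as the interaction, the difference between the log2 response to BMP2 with and without activin A. Additivity here means that the folds multiply, and a sum of the rises in intensity was not tested. No gene passed limma's test, with 271 at an unadjusted p under 0.05, where 596 would be expected by chance. A count this low means that the lack of calls does not show additivity, and counts with a replicate block are given below. The smallest p belonged to Ttr (-2.95 ± 0.35), Apoe (-2.76 ± 0.36) and Rbp4 (-2.71 ± 0.36), each with adjusted p = 0.67, and on the positive side to Tubb3 (2.43 ± 0.40), Thbd (1.23 ± 0.23) and Nacad (3.94 ± 0.81). For Ttr the levels were 8.36 untreated, 10.60 with activin A, 11.14 with BMP2 and 10.43 with both. As lists, visceral endoderm (median -1.37), epithelial junctions (-0.44) and lipid handling (-0.41) lay below additivity, with camera adjusted p of 1.14e-18, 3.64e-06 and 0.00447, and adjusted p = 0.592 with an estimated correlation for each. The visceral endoderm median was -1.13 with the replicate 1 arrays of untreated and BMP2 and -1.27 with their replicate 2 arrays. Both values use the same lone arrays. It was -0.803 without untreated replicate 1 and -0.735 without BMP2 replicate 2. Leaving out untreated replicate 1 or 2 gave 6 or 3 called genes instead of 0, and without BMP2 replicate 2 the lipid list was not called (-0.276, adjusted p = 0.0766). Other lists were called when 1 array was left out: cholesterol (0.396) and trophoblast (0.894) without untreated replicate 1, endocytosis (-0.092) and interferon (-0.303) without untreated replicate 2, cholesterol (-0.31), endocytosis (-0.132) and interferon (-0.135) without BMP2 replicate 1, and cholesterol (0.619) and unfolded protein (0.181) without BMP2 replicate 2. The parietal endoderm list was called upward with the deposited scaling (0.187) and with array medians aligned (0.271). Aligned medians also called basement membrane (0.264) upward and interferon (-0.17) downward.

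Of the 64 genes raised by BMP2, 60 lay above both untreated arrays in the activin array, and 64 did so in the combined array. For an unchanged array the shared untreated arrays gave 36.5% in simulation, against 93.8% observed with activin A. The median change of these genes was 2.14 with BMP2, 0.96 with activin A and 2.05 with both. Of the 19 lowered genes, 14 lay below both untreated arrays with activin A (73.7%, against 41.2% simulated) and 19 with both. All 12 genes raised by the combined treatment were among those raised by BMP2, and Vegfc was lowered in both. With the untreated arrays shared, the 12 higher genes with the smallest p in a simulated unchanged combined array held 0.65 such genes on average and at most 2 in 20 draws. These simulations drew genes as independent and without a shift between replicates. Genes that vary together could move to one side in 1 array, so the simulated values do not give the full range of chance.

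Across all genes, which are not independent replicates, the BMP2 and activin responses correlated at r = 0.499 with a covariance of 0.0967. Unchanged groups against the shared untreated arrays gave r = 0.408 and a covariance of 0.0401 in simulation, a difference in covariance of 0.0566. With a separate untreated array for each treatment, r was 0.0552 with untreated replicate 1 for BMP2 and 0.279 with untreated replicate 2 for BMP2. The BMP2 and combined responses correlated at r = 0.757 (covariance 0.189, against 0.04 simulated), and at 0.349 and 0.513 with separate untreated arrays. Each side of those splits kept only 1 untreated array. The splits also differ in how the shift of the replicate 2 arrays enters. Untreated replicate 1 for BMP2 leaves untreated replicate 2 for the other response. The shift then enters the responses with opposite signs, which lowers r. In that split the BMP2 and activin responses had the same sign in 46.3% of genes, against 59.8% in the other split.

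**Figure D3:**
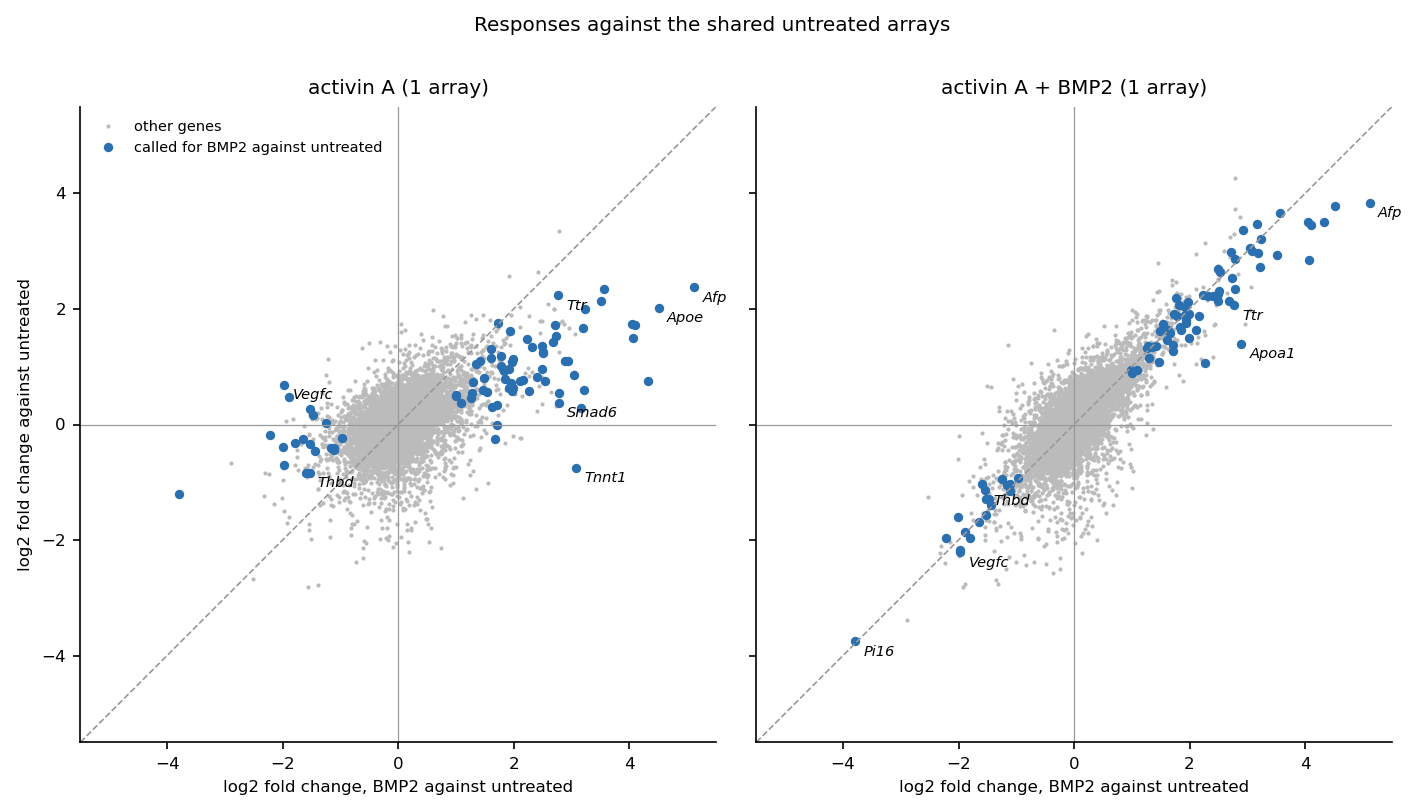
Log2 fold change against the untreated arrays for each of the 11925 genes, BMP2 on the horizontal axis and activin A (left) or the combined treatment (right) on the vertical axis, with the 83 genes called for BMP2 in blue, the others in grey and a dashed line at equal change. Among called genes, Gldc lies at 1.73 with BMP2 and 1.76 with activin A, Tnnt1 at 3.08 and -0.75, and Plet1 at 2.27 with BMP2 and 1.07 with the combined treatment.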

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

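The tests in this part were chosen after the results were seen. In the test of the interaction, 3 gene lists departed from additivity: visceral endoderm (median -1.37 on the log2 scale), epithelial junctions and keratins (-0.439) and lipid handling (-0.407). For these lists the log2 response to both ligands was smaller than the sum of the separate log2 responses, by camera with a preset correlation. For genes raised by both ligands, a sum of the rises in intensity would predict a smaller response than this. Part of the shortfall may therefore come from the log2 scale, which was not tested. None of the 3 held by camera with an estimated correlation (adjusted p = 0.592), a form that called no list in any comparison. The lipid list was not called without BMP2 replicate 2 (-0.276), and the activin and combined values are 1 array each.

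For the visceral endoderm list, 2 technical explanations were weighed. An intensity ceiling common to all probe sets would put the genes near the top of the scale in the combined array. Of the 16 genes with an interaction below -1, however, 0 lay within 1 log2 unit of the brightest probe set (highest 11.71, against 13.56). A ceiling that differs between probe sets was not tested. BMP2 replicate 2 alone could not account for the whole of it. The replicate 1 arrays of untreated and BMP2, with the lone arrays, gave a median of -1.13. The fit without BMP2 replicate 2 gave -0.735, and both were further from 0 than the gap of 0.22 between the untreated arrays. What stays open is whether another activin or combined array would stand where these do, and how much of the shortfall comes from the log2 scale. A limit to the shared response to the ligands may remain as an untested biological explanation. In levels, 20 of the 27 genes were lower in the combined array than in both BMP2 arrays.

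Among probe sets that the comparisons did not use, a fit of all kept probe sets called 10 of 3888 without a gene symbol for BMP2 against untreated, 5 of them higher, with changes from -2.44 to 3.96 on the log2 scale. It called 1 of 610 probe sets that name several genes, with a rise of 2.25, and 0 of 37 control probe sets.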

How the results depend on the processing

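Of the tests in this part, only the block that places the lone arrays with replicate 1 was chosen after the results were seen. For BMP2 against untreated (83), 8 alternatives that kept the replicates gave 72 to 106 genes, but a prior without the intensity trend gave 0 and no filter gave 29. The former prior weighs less (2.82 against 4.69 degrees of freedom) and its smallest adjusted p was 0.0628. For the combined treatment against untreated (13), the counts were 0 without the trend, 0 without the filter and 27 with array medians aligned, a scaling that moved the median of all genes for BMP2 from -0.0179 to -0.106. The cause was not tested. Leaving out a replicate, which leaves 1 residual degree of freedom and lone arrays assumed to vary like the rest, gave 21 to 330 genes for BMP2, 0 to 32 for activin A and 29 to 252 for the combined treatment against untreated. It gave 0 to 1 for the combined treatment against BMP2, 0 to 23 against activin A and 0 to 6 for the interaction. The correlation of the BMP2 and activin responses (0.499) was 0.0552 or 0.279 with separate untreated arrays. The shift of the replicate 2 arrays lowers the former.

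The labels give untreated and BMP2 arrays the same replicate numbers. Their replicate differences correlated at r = 0.337, with the same sign in 66.6% of genes, and at 0.557 under the 60th percentile filter. The replicate 2 arrays thus shared a shift, but the labels do not say what the number stands for, and there are only 2 pairs. The replicate block set the lone arrays midway between the replicates. By median absolute log2 difference, the activin array lay closer to untreated replicate 1 (0.157) than to replicate 2 (0.262). The combined array lay closer to BMP2 replicate 1 (0.138) than to replicate 2 (0.243). Block counts for activin A and the combined treatment against untreated therefore rest on where the lone arrays are placed. With a replicate block, 981 genes were called for BMP2, 97 for activin A and 617 for the combined treatment against untreated, 70 for the combined treatment against activin A, 13 for the interaction and 0 against BMP2. A block that places the lone arrays with replicate 1 gave 981, 26, 381, 70, 13 and 0 in that order.

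The cholesterol list turned direction: for the combined treatment against BMP2 (-0.273) its median was 0.102 without BMP2 replicate 2, -0.717 without BMP2 replicate 1 and 0.038 with the block placing lone arrays, and for the interaction (0.164, not called) it was -0.31 without BMP2 replicate 1 and 0.619 without BMP2 replicate 2. The cause was not tested. No called gene named by the rule changed direction under any alternative. Of their values, 547 stayed past the threshold and 109 did not. Of the values of called lists, 542 stayed called in the same direction, 54 did not pass and 2, both of the cholesterol list, turned in camera's direction. Among those that did not pass, the BMP-Smad list for the combined treatment against untreated (0.114) had a median of -0.061 with the mean of a gene's probe sets, although camera's direction stayed upward. No detection calls were used, so signal over background limits the dim genes.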

Other observations

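Of the tests in this part, those of the untreated arrays, a fixed share, wells, intensity distribution, RNA degradation and the responses seen again were chosen after these or related results were seen, and only that of dim probe sets before. Some further genes called for BMP2, other than the troponin genes, were chosen for naming after their values were seen. Membrane-anchored and secreted serine proteases and their inhibitors were among them: Tmprss2 rose by 2.50 ± 0.27, Prss8 by 2.52 ± 0.31, St14 by 1.97 ± 0.20, and the inhibitors Spint1 by 2.16 ± 0.22 and Spint2 by 2.41 ± 0.28 (log2, SE). Of junction and epithelial surface genes, Ocln rose by 2.49 ± 0.21, Cgn by 1.81 ± 0.24 and Epcam by 1.27 ± 0.19. The troponin genes Tnnc1 and Tnnt1, which encode proteins of striated muscle, rose by 2.54 ± 0.19 and 3.08 ± 0.41. Csf1r, the receptor of macrophage colony-stimulating factor, rose by 1.99 ± 0.22, the transcription factor gene Zbtb16 by 1.71 ± 0.24, and Timp3, an inhibitor of metalloproteinases, by 1.99 ± 0.14. The glycine-cleavage gene Gldc rose by 1.73 ± 0.22 with BMP2 and stood at 1.76 in the activin array, while Tnnt1 stood at -0.75 there. No enrichment was tested for these genes. Apart from the troponin genes, they were not followed individually when a BMP2 replicate was left out. Most genes called for BMP2 did not pass without BMP2 replicate 1 or 2, so the calls of these further genes may not hold there either.

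A hypothesis was that the BMP2 response recurs when BMP2 is added to activin A, in arrays that did not choose its genes. Of the 83 genes called for BMP2, 82 had the same sign in the combined array minus the activin array, against 62.6% of all genes. The median of the raised genes was 1.07 there and that of the lowered genes -1.22, so this set of genes may respond to BMP2 in the presence of activin A too. Before this count, the correlation of these responses over all genes (r = 0.419) and the values of several named genes had been seen. The counterpart for activin A was not seen in these counts. Its correlation over all genes had been seen too (r = 0.119). It was -0.0417 against the replicate 1 arrays of untreated and BMP2 and 0.326 against their replicate 2 arrays. Both values use the same lone arrays. In the latter both responses carry the shift of the replicate 2 arrays, which raises r. Of the 100 genes with the smallest p for activin A against untreated, 48 had the same sign in the combined array minus BMP2 replicate 1 (46.2% of all genes) and 53 against BMP2 replicate 2 (60.5% of all genes).

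Genes raised by BMP2 stood higher in the activin array as well, 60 of 64 above both untreated arrays (93.8%, against 36.5% for a simulated unchanged array sharing them). The simulation drew genes as independent, so it does not cover genes that vary together between wells. RNA of BMP2-treated cells in the activin sample at a fixed share was weighed. At the best share of 26%, 15 of the 64 genes lay over 2 errors away, with Smad6 and Tnnt1 below it and Ttr and Gldc above it. The upper limit was 10 for independent genes. A fixed share was argued against only on that assumption, since genes that vary together could exceed the limit. Error of the untreated arrays was not excluded by a first test, in which 18 of the 27 visceral endoderm genes lay above both of them, against a median of 10 and a highest count of 21 in 10000 random lists matched on level, although its median of 0.674 exceeded the highest of theirs (0.382), which lack the correlation of 0.258 among its genes. Nor was it by a test that replaced the first after that outcome: 69.6% of the 194 genes called for BMP2 without untreated replicate 2 lay above that array with activin A (51.1% of all genes), under the bound of 75%, while the reverse choice gave 87.6% of 242 (48.8% of all genes). A response to activin A and variation between wells cannot be told apart with 1 activin array.

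The replicate 2 arrays of the untreated and BMP2 groups departed from the other arrays in the same direction. A difference in intensity distribution was argued against, since the replicate differences of the 2 groups still correlated at 0.337 after quantile normalisation, and so was noise of dim probe sets, with 0.557 under the 60th percentile filter. RNA degradation remained open: of 2 control genes with probe sets at both ends, 1 (Actb, with 3'-to-5' ratios of 1.28 and 1.27, against 1.23 to 1.26) set both replicate 2 arrays outside the others, and Gapdh did not. A separate culture or processing day was not tested, and no biological explanation was tested.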
